A study of Mus musculus with 6 samples.

How the data were processed

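Total RNA was isolated with Trizol and treated with DNase I, and 300 ng was labelled with biotin for the Affymetrix mouse Gene 1.0 ST array, per the labels' protocols. The 6 samples, 3 control and 3 VPA, were grouped by their titles and numbered as there. The fields for source, strain and cell type name differentiated and undifferentiated embryonic stem cells with the same division of the samples, and they were not used to set a group. The deposited values are on the log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. Versions of these programs and the genome build are not given in the sources used here. The values were used as deposited. RMA forces the arrays to one distribution, so a shift of most transcripts in one direction would not show, and it leaves no measure of signal over background, so low values have no detection call.

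Of 35556 probe sets, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several and 12146 were not listed there. Probe sets with several symbols named no gene, which leaves Cdkn1a without a value. Symbols were looked up by Entrez identifier in a RefSeq table of assembly GRCm38.p6, which matched 21698 probe sets and changed 0 symbols, and 91 kept the symbol of the annotation. One probe set was kept for each gene, that with the highest mean over the 6 arrays, which gave 19938 genes, 999 of which had more than 1 probe set. Of 12 changed genes with several probe sets, 1 had a probe set of opposite sign. No other filter was set.

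The comparison of VPA with control used lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values, with the group as the only term, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p under 0.05, and a log2 difference of at least 1 was a second criterion. Because the test borrows variance across genes, its prior had 5.49 degrees of freedom for the genes tested. Ccnd2 was also tested with an exact permutation test. The 26 gene lists, with 792 entries of which 729 matched a tested gene, were written from general knowledge of histone deacetylase inhibition, the cell cycle, the prostate, stem cells and other cell types. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. List entries without a match were not used here.

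The genes named in the text follow a rule, except where the text says otherwise. Ccnd2, Ccnd1, Ccnd3, Cdkn1a, Hdac1 and Hdac2 were to be named in any case. In each direction the 12 changed genes with the largest differences were named, if the groups did not overlap, leaving out predicted or unnamed genes, olfactory and vomeronasal receptors, small RNAs and receptor segments. From each list up to 3 changed members in each direction were named, or the 2 with the smallest p where none changed, along with the sex-chromosome genes and Pou5f1, Nanog, Sox2 and Zfp42. The groups, the tests of genes and lists, the lists, this rule and the alternative settings were fixed before the data were examined, except for the comparison without control replicate 2 and VPA replicate 3. The tests of explanations came later, and the closing section names those chosen after their result was seen.

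The alternatives were a filter that kept genes with a log2 value of at least 6 in at least 3 arrays, a second quantile normalization, centring of arrays on their medians, an intensity trend with a robust prior, the replicate number as a block, array weights, the mean of a gene's probe sets, all probe sets of the table, an ordinary t-test, an adjusted p under 0.01 and leaving out each array in turn. The test was tested on simulated data of the same size, in which 200 of 19938 genes were changed. It called 100% of those changed by 1 on the log2 scale and 98% of those changed by 0.7, with 12 false calls among 210, and it made 0 calls in simulated data without change. The simulated noise was normal and independent between genes and arrays, with no array lying between the groups. These rates therefore do not give the power in the real arrays.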

Results

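Messenger RNA levels were measured in murine prostate cancer cells treated with valproic acid (VPA) and in control cells, as the sample titles and the series design name them. VPA is a branched short-chain fatty acid used against epilepsy and bipolar disorder, and it inhibits class I histone deacetylases, the enzymes that remove acetyl groups from histones. The 6 samples, 3 control and 3 VPA, were described as biological replicates, and each was hybridised to its own Affymetrix mouse Gene 1.0 ST array. Dose, duration and the name of the cell line are not given in the sources used here. The source, strain and cell type fields of the same samples name differentiated and undifferentiated embryonic stem cells of different strains, with the same division of the samples. The groups carry the names in the titles here, and every VPA minus control difference rests on these titles. The arrays held log2 values of 35556 probe sets, with medians from 7.15 to 7.18, and 19938 genes were tested. The number of arrays, 3 per group, limits the precision, with a median standard error of 0.101 on the log2 scale.

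The title of the series names cyclin D2, a D-type cyclin that binds CDK4 and CDK6 in the G1 phase, and the comparison asks whether its transcript differs between VPA-treated and control cells. Ccnd2 mRNA (probe set 10548105) was higher with VPA, at a log2 value of 10.68 ± 0.37 (SD, n = 3) against 9.34 ± 0.38 (SD, n = 3) in the control arrays. The log2 difference was 1.34 (SE 0.212), or 2.53-fold with a 95% interval from 1.82 to 3.52. It passed the moderated test of limma over all genes with an adjusted p of 0.0175. The 3 VPA values, from 10.40 to 11.10, lay above the 3 control values, from 8.97 to 9.73. The exact two-sided permutation test of these 6 values gave p = 0.1, the smallest that 3 against 3 values allow. The other D-type cyclins did not pass: Ccnd1 differed by -0.44 (SE 0.142, adjusted p = 0.146) and Ccnd3 by 0.26 (SE 0.107, adjusted p = 0.239). The deacetylase genes Hdac1, at 0.10 (SE 0.0889, adjusted p = 0.591), and Hdac2, at 0.13 (SE 0.0895, adjusted p = 0.462), did not pass either. Of 28 measured genes of a cell cycle list (cyclins, cyclin-dependent kinases, their inhibitors, and E2F and Rb family genes), Ccnd2 was the 1 that rose, none fell and 27 did not pass, over all genes and adjusted over the list alone. Without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2 the Ccnd2 difference was 1.16, 1.33, 1.13 or 1.41, and its adjusted p was 0.0719, 0.0682, 0.058 or 0.0608. The call also ended with every probe set of the table tested, at 0.151, and with variances not moderated across genes, at 0.253.

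**Figure D1:**
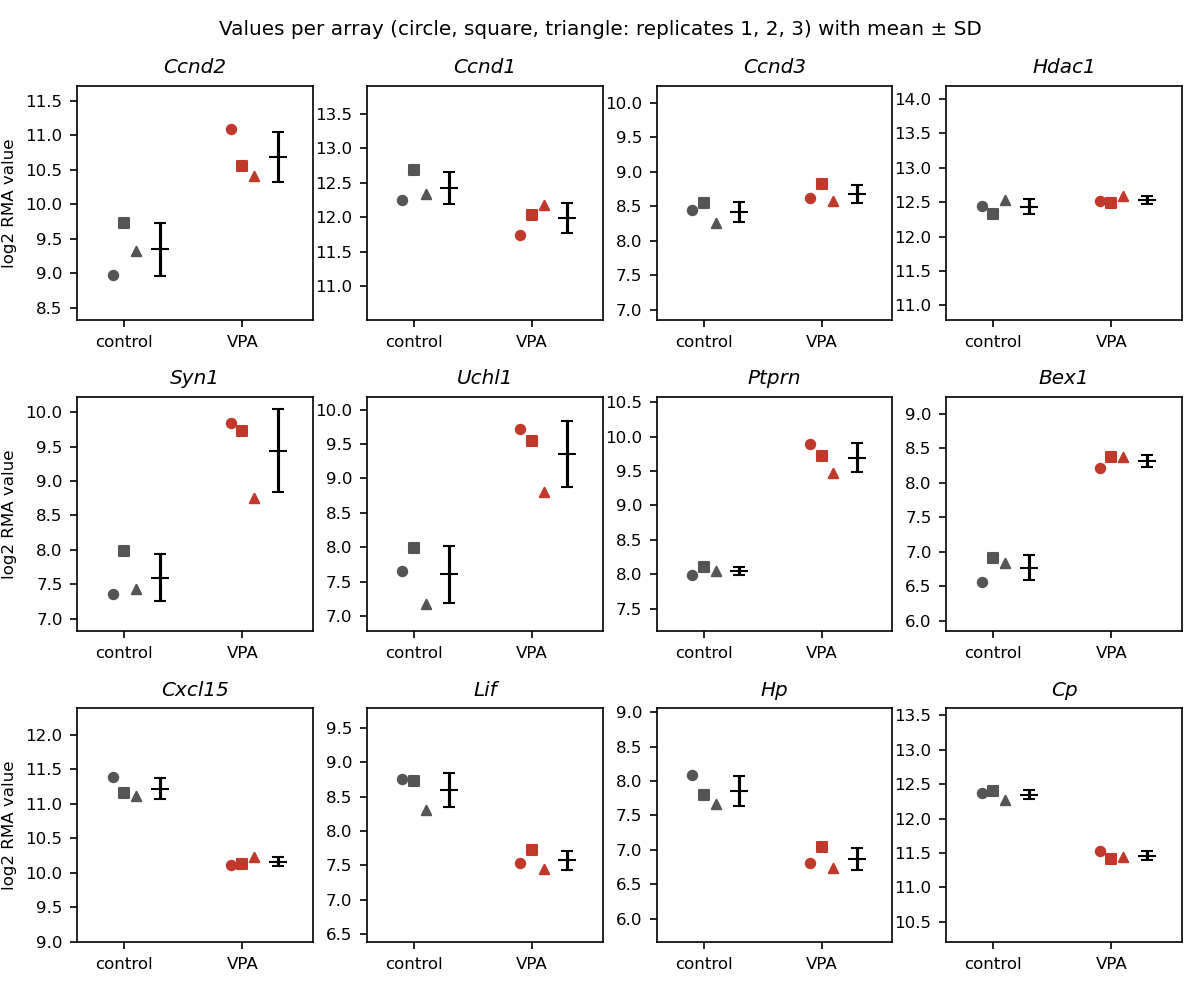
Log2 RMA values (vertical axis, log2 units) of 12 genes in the control and VPA arrays, with one symbol per array and the mean ± SD of 3 arrays beside them. Each panel spans the same number of log2 units, and Ccnd2 lies between 8.97 and 9.73 in the control arrays and between 10.40 and 11.10 in the VPA arrays.

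Of the 42 measured genes of the neuronal and neuroendocrine list, 11 rose with VPA, none fell and 31 did not pass. Syn1, which encodes a phosphoprotein of synaptic vesicles, rose 3.59-fold (log2 1.85, SE 0.27, n = 3 per group, limma adjusted p = 0.0146). Uchl1, a ubiquitin hydrolase abundant in neurons, rose 3.36-fold (log2 1.75, SE 0.249, adjusted p = 0.0139). Bex1, an X-linked gene expressed in brain, rose 2.93-fold (log2 1.55, SE 0.108, adjusted p = 0.000962). Adjusted over the list alone, 16 rose and 1 fell. The mean difference was 0.35 and the median 0.18, and the list passed limma's camera test with a preset correlation at an adjusted p of 2.01e-08. It did not pass with a correlation estimated from its own residuals, at an adjusted p = 0.574 with an estimated correlation. Relative to the mean of the 6 arrays, the list lay at -0.19, -0.18 and -0.15 in control replicates 1, 2 and 3 and at 0.28, 0.17 and 0.08 in VPA replicates 1, 2 and 3. Syn1 and Uchl1 lost their calls without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2 (adjusted p 0.0703, 0.0574, 0.058 or 0.0615 and 0.0597, 0.051, 0.0571 or 0.0608), whereas Bex1 stayed past the threshold whichever single array was left out.

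Over all genes, 467 changed at an adjusted p under 0.05, of which 341 were higher and 126 lower with VPA, so that 73% of the changed genes were higher. This share depended on the setting. It was 66.7% with the arrays centred on their medians, 67.3% with a second quantile normalization and 81.9% without control replicate 2. At least 2-fold changes were found for 52 of the 467 genes, 47 higher and 5 lower. The median size of change among the 467 was 0.645 on the log2 scale, and the median difference over all genes was -0.035. At an unadjusted p under 0.05 there were 3611 genes against 997 given by chance, and the groups did not overlap in 4614 genes (23.1%), against 10% by chance. The count of changed genes moved with single arrays: it was 20 without control replicate 1, 71 without control replicate 3, 66 without VPA replicate 1, 72 without VPA replicate 2 and 815 without VPA replicate 3. The count was 2 with every probe set of the table tested and 0 with unmoderated variances, where 2898 genes had an unadjusted p under 0.05.

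Besides Ccnd2, Syn1, Uchl1 and Bex1, the largest increases included a receptor-like phosphatase of dense-core vesicles, an ephrin and a detoxifying enzyme. Ptprn, the vesicle protein, rose 3.13-fold (log2 1.64, SE 0.114, n = 3 per group, limma adjusted p = 0.000962). Efna3, which encodes ephrin-A3, a ligand of Eph receptors, rose 2.67-fold and the palmitoyltransferase gene Zdhhc9 2.66-fold, with adjusted p of 0.0139 and 0.0275. Gsta4, a glutathione transferase that acts on lipid peroxidation products, rose 2.61-fold and Plag1, a zinc finger transcription factor gene, 2.58-fold (adjusted p 0.00719 and 0.00853). Tmem255a rose 2.56-fold, Stmn2, a regulator of microtubules in neurons and a member of the neuronal list, rose 2.52-fold and Lce3c, of the late cornified envelope family, also rose 2.52-fold (adjusted p 0.0259, 0.0163 and 0.00973). With a trended and robust prior the adjusted p of Zdhhc9 was 0.0507.

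Among the genes with the largest decreases, the chemokine gene Cxcl15 fell by 1.05 on the log2 scale (SE 0.0985, n = 3 per group, limma adjusted p = 0.00702), from 11.22 ± 0.15 to 10.16 ± 0.06 (SD). Lif, the cytokine leukaemia inhibitory factor, fell by 1.02 (SE 0.132, adjusted p = 0.00993). The haptoglobin gene Hp fell by 0.99, Masp1, a protease of the lectin pathway of complement, fell by 0.97, and Cp, which encodes the copper-binding ferroxidase ceruloplasmin, fell by 0.88 (adjusted p 0.00993, 0.00859 and 0.00702). Slc22a22, of the organic ion transporter family, fell by 1.34 and Rcbtb2 fell by 1.15 (adjusted p 0.00973 and 0.0153). The leukocyte tetraspanin gene Cd53, Gdpd2, Cyp26a1, whose product degrades retinoic acid, and Jade2 fell by 0.88, 0.88, 0.83 and 0.82 (adjusted p 0.0373, 0.00993, 0.0212 and 0.0117). Cd53 passed in 8 of 16 settings and lost its call without any single array other than VPA replicate 3. H2bc4, a histone H2B gene, fell by 1.01 (adjusted p = 0.0372), but near-identical H2B copies can share its probes, so this value is uncertain. Of the 38 changed genes named here besides Ccnd2, 8 stayed past the threshold without control replicate 1, 34 without control replicate 2, 16 without control replicate 3, 16 without VPA replicate 1, 15 without VPA replicate 2 and 38 without VPA replicate 3. The 8 genes Bex1, Cd36, Cp, Cxcl15, Gsta4, Plag1, Ptprn and Thy1 stayed past it whichever single array was left out.

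Of 29 measured genes of fatty acid oxidation and the peroxisome, 2 rose with VPA, none fell and 27 did not pass. Cd36, a fatty acid uptake receptor, rose 2.46-fold (log2 1.30, SE 0.128, n = 3 per group, limma adjusted p = 0.00702). Hadh, a dehydrogenase of mitochondrial beta-oxidation, rose 1.53-fold (log2 0.62, SE 0.104, adjusted p = 0.0223). Adjusted over the list alone, 6 rose and 1 fell. The camera test gave an adjusted p of 4.59e-04 (mean difference 0.16), but adjusted p = 0.574 with an estimated correlation. The list lay at -0.129, -0.000428 and -0.112 in control replicates 1, 2 and 3 and at 0.07, 0.10 and 0.07 in the VPA replicates, so control replicate 2 lay between the other controls and the VPA arrays. Hadh lost its call without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2 (adjusted p 0.0947, 0.0792, 0.0844 or 0.0915).

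Among 27 measured target genes of the tumour suppressor p53, 2 rose, none fell and 25 did not pass. Ddb2, a sensor of damaged DNA, rose 1.52-fold (log2 0.60, SE 0.101, limma adjusted p = 0.0222) and Dram1, a regulator of autophagy, rose 1.42-fold (log2 0.50, SE 0.0994, adjusted p = 0.0367). Adjusted over the list alone, 2 rose and 1 fell, and the camera test gave an adjusted p of 0.00703 (mean difference 0.13), but adjusted p = 0.673 with an estimated correlation. In control replicate 2 the list lay at 0.05, above VPA replicate 3 at 0.03, and without VPA replicate 2 its camera adjusted p was 0.0527. Of 30 measured genes of the DNA damage response and repair, the checkpoint kinase gene Chek2 rose 1.35-fold (log2 0.43, SE 0.081, adjusted p = 0.0304), none fell and 29 did not pass. Adjusted over the list alone, 5 rose and 1 fell. Its camera adjusted p was 0.0144 (mean difference 0.09), but adjusted p = 0.574 with an estimated correlation, and quantile normalization of the 6 arrays a second time gave 0.215. Ddb2, Dram1 and Chek2 lost their calls without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2, with adjusted p of 0.0989, 0.079, 0.0819 or 0.0915 for Ddb2, 0.105, 0.108, 0.125 or 0.102 for Dram1 and 0.133, 0.0872, 0.121 or 0.118 for Chek2. Dram1 passed in 8 of 16 settings (adjusted p from 0.0129 to 0.226) and also lost its call without control replicate 2 (0.0679) and with quantile normalization a second time (0.0506).

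Of 20 measured genes of antigen presentation by MHC class I, 3 fell with VPA, none rose and 17 did not pass. The class I genes H2-K1, H2-D1, H2-Q7, H2-T23 and H2-T22 had no tested value, so the list does not cover them. B2m, H2-Q4 and H2-M3, named outside the rule after the result was seen, differed by 0.05, 0.01 and -0.13. None of these passed (adjusted p 0.786, 0.945 and 0.546). Of the 3 that fell, Erap1, which trims peptides in the endoplasmic reticulum, fell by 0.81 on the log2 scale (SE 0.115, n = 3 per group, limma adjusted p = 0.0139). Psmb10, a subunit of the immunoproteasome, fell by 0.74 and Tapbpl, a peptide editor of MHC class I, fell by 0.67 (SE 0.106 and 0.0975, each with an adjusted p of 0.0139). The count that fell was 4 adjusted over the list alone. The camera test gave an adjusted p of 0.00703 (mean difference -0.21), but adjusted p = 0.574 with an estimated correlation. The 3 genes that fell lost their calls without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2, with adjusted p of 0.0703, 0.0534, 0.058 or 0.0608 for Erap1, 0.0577, 0.0534, 0.058 or 0.0613 for Psmb10 and 0.0703, 0.0534, 0.058 or 0.062 for Tapbpl.

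Of 30 measured interferon-stimulated genes, 3 fell, none rose and 27 did not pass. These were Parp14 and Parp9, of the ADP-ribosyltransferase family, which fell by 0.82 and 0.74, and Irgm1, an immunity-related GTPase gene, which fell by 0.79 (adjusted p 0.0455, 0.0484 and 0.0432). All 3 lost their calls without control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2, with adjusted p of 0.171, 0.146, 0.14 or 0.157 for Parp14, 0.178, 0.156, 0.176 or 0.176 for Parp9 and 0.154, 0.138, 0.131 or 0.141 for Irgm1. Parp9 also lost its call with quantile normalization a second time (0.0518) and passed in 9 of 16 settings (adjusted p from 0.00394 to 0.3). The counts adjusted over the list alone were 8 that fell and 1 that rose. The camera adjusted p was 0.0281 (mean difference -0.18), but adjusted p = 0.722 with an estimated correlation. The list lay at 0.28, -0.16 and 0.15 in control replicates 1, 2 and 3 and at 0.00174, -0.267 and -0.00938 in the VPA replicates, so control replicate 2 lay below VPA replicates 1 and 3. Its camera adjusted p was 0.411 without control replicate 1, 0.0831 without control replicate 3, 0.184 without VPA replicate 2 and 0.0517 with the arrays centred on their medians. For 35 measured genes of mitosis the mean difference was -0.12 and the camera adjusted p 0.0144, but adjusted p = 0.722 with an estimated correlation. None of them passed limma's test by itself, over all genes or adjusted over the list alone, and 8 had lower values at an unadjusted p under 0.05. Kif20a and Kif2c, both mitotic kinesin genes, differed by -0.36 and -0.38 (adjusted p 0.0795 and 0.149). VPA replicate 3, at 0.05, lay among the controls for mitosis, and the camera adjusted p was 0.0809 without control replicate 1 and 0.191 without VPA replicate 1.

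**Figure D2:**
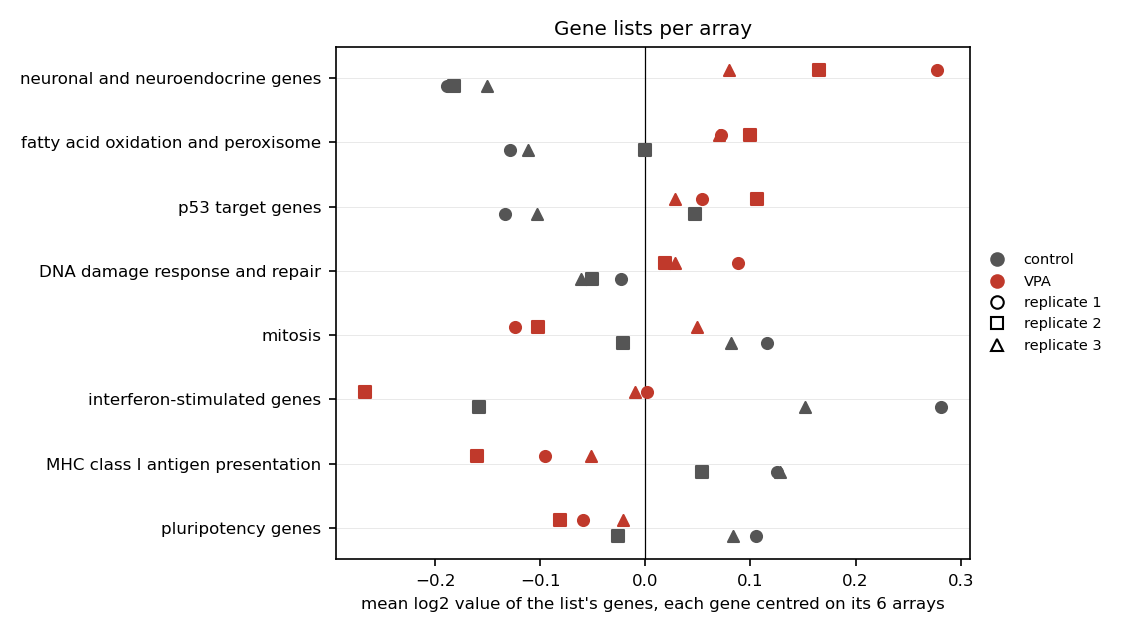
Mean log2 value of the measured genes of 8 gene lists (horizontal axis, log2 units, each gene centred on its mean over the 6 arrays) for each control and VPA array. For the neuronal list the control arrays lie between -0.19 and -0.15 and the VPA arrays between 0.08 and 0.28, while the groups overlap for the p53, mitosis, interferon and pluripotency lists.

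Of the 26 lists, 7 passed the camera test with the preset correlation, 4 of them higher and 3 lower with VPA. With an estimated correlation none passed and 1 had an unadjusted p under 0.05, and with limma's fry, which tests whether a list moves one way on balance, none passed and 4 had an unadjusted p under 0.05. In fry's test for change in either direction 11 lists passed. The lowest adjusted p, 0.000696, was shared by the neuronal list and the list of histone deacetylases and acetyltransferases. Without control replicate 2, 14 lists passed camera.

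The other lists did not pass camera, though some held changed members. Of 44 measured mesenchymal and extracellular matrix genes, Thy1, a surface glycoprotein of fibroblasts and neurons, rose 1.99-fold (log2 0.99, limma adjusted p = 0.00973). The collagen VI genes Col6a2 and Col6a1 fell by 0.62 and 0.41 (adjusted p 0.0252 and 0.0479), and 41 did not pass. Adjusted over the list alone, 2 rose and 6 fell, and the camera adjusted p was 0.185. Of 21 immune cell genes Coro1a, which encodes an actin-binding protein of leukocytes, rose 1.75-fold (adjusted p = 0.0187) over all genes and adjusted over the list alone, with a camera adjusted p of 0.451. Of 14 measured polyadenylated and replication-independent histone genes H2bc4 alone changed, over all genes and adjusted over the list alone, with a camera adjusted p of 0.256. H2bc4 passed in 9 of 16 settings and lost its call without any single array other than VPA replicate 3. Leaving out control replicate 1, control replicate 3, VPA replicate 1 or VPA replicate 2 ended the calls of Col6a2 (adjusted p 0.0784, 0.0895, 0.107 or 0.104), Col6a1 (0.174, 0.122, 0.163 or 0.18) and Coro1a (0.0888, 0.0717, 0.0602 or 0.0769), and Col6a1 also lost its call without control replicate 2 (0.0686).

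In the remaining lists no member passed limma's test over all genes. Among 27 histone deacetylase and acetyltransferase genes, 2 were higher and 6 lower at an unadjusted p under 0.05, with the acetyltransferase gene Kat2b at -0.35 (adjusted p = 0.0949), the deacetylase gene Sirt2 at 0.31 (adjusted p = 0.0966) and the list at a camera adjusted p of 0.777. In fry's test for change in either direction this list passed, at an adjusted p of 0.000696. So did the lists of apoptosis (0.0108), Polycomb and chromatin modifiers (0.0323), ribosome biogenesis (0.0418) and the unfolded protein response (0.0418). The counts at an unadjusted p under 0.05 were 1 higher and 4 lower among 39 DNA replication genes, where Tk1, thymidine kinase, was at -0.51 and Uhrf1 at -0.22 (adjusted p 0.065 and 0.206), and 0 higher and 7 lower among 33 genes of ribosome biogenesis and Myc targets, where Gnl3 was at -0.44 and Nhp2 at -0.36 (adjusted p 0.0973 and 0.104), with camera adjusted p of 0.145 and 0.053. They were 1 higher and 0 lower among 23 prostate and androgen-related genes, whose Hoxa13 was at 0.40 and Fkbp5 at 0.16 (adjusted p 0.138 and 0.336), and 3 higher and 4 lower among 39 epithelial genes, whose Muc1, a mucin gene, was at -0.48 and Itgb4 at -0.40 (adjusted p 0.0596 and 0.0874), with camera adjusted p of 0.538 and 0.185. For 32 apoptosis regulators they were 4 higher and 4 lower, with Diablo, an inhibitor of apoptosis inhibitors, at 0.57 and Cflar at -0.41 (adjusted p 0.0518 and 0.113), a camera adjusted p of 0.74 and 1 that rose adjusted over the list alone. For 20 cholesterol biosynthesis genes they were 1 higher and 1 lower, and for 29 glycolysis and hypoxia genes 2 higher and 0 lower, with camera adjusted p of 0.538 and 0.74. Dhcr7 and Cyp51, of sterol synthesis, were at 0.51 and -0.26 (adjusted p 0.127 and 0.263), and the phosphofructokinase genes Pfkp and Pfkm at 0.53 and 0.41 (adjusted p 0.181 and 0.239). For 26 genes of the unfolded protein response they were 2 higher and 1 lower, and for 32 Polycomb, DNA methylation and chromatin modifier genes 5 higher and 2 lower, with camera adjusted p of 0.295 and 0.576. Vldlr and Atf3 of the first list were at -0.48 and 0.74 (adjusted p 0.0627 and 0.0964), and Sin3a and Cbx7 of the second at 0.31 and 0.26 (adjusted p 0.103 and 0.203). For 16 endothelial genes they were 1 higher and 1 lower, with Tek at 0.42 and Cldn5 at -0.30 (adjusted p 0.182 and 0.208) and a camera adjusted p of 0.396. The mean and the median differed in sign for the glycolysis list (0.00103 and -0.0178), where camera pointed up and fry down, and for the Polycomb list (0.00754 and -0.0181), where both pointed up. Apart from Diablo, none of these lists had a member that passed adjusted over the list alone.

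A further set of genes was read as a check of the conflicting labels. Pou5f1, Nanog, Sox2 and Zfp42, transcription factor genes of pluripotent cells, differed by -0.36, -0.20, -0.32 and -0.14, and none of them passed limma's test (adjusted p 0.225, 0.353, 0.26 and 0.438). Their mean was 6.98 ± 0.0956 (SD, n = 3) in the control arrays and 6.72 ± 0.124 in the VPA arrays, a difference of -0.26 (SE 0.09). Among 28 measured pluripotency genes none passed, 1 was higher and 5 lower at an unadjusted p under 0.05, and the camera adjusted p was 0.0616. The smallest p in this list were those of Fgf4, at -0.33, and Trim71, at -0.27 (adjusted p 0.0997 and 0.198). Among 29 genes of early germ layer differentiation none passed, 1 was higher and 3 lower at an unadjusted p under 0.05, and Nes, an intermediate filament gene of neural progenitors, was at 0.45 and Gsc at -0.27 (adjusted p 0.129 and 0.141). Among 29 germline genes none passed and 3 were lower at an unadjusted p under 0.05, with Tdrd9 at -0.34 and Slc25a31 at -0.25 (adjusted p 0.0987 and 0.207). Camera adjusted p were 0.229 for germ layer and 0.185 for germline genes, and no member of the 3 lists passed adjusted over the list alone. Of the 7 sex-chromosome genes none passed, over all genes or adjusted over the list alone, 1 was lower at an unadjusted p under 0.05, and the camera adjusted p was 0.451. Xist, the RNA that coats the inactive X chromosome, had a log2 value of 5.36 ± 0.12 in control and 5.32 ± 0.11 in VPA arrays (SD, n = 3). The Y-linked genes Eif2s3y, Kdm5d and Uty were at 9.84, 9.16 and 9.36 in control and 9.92, 9.13 and 9.06 in VPA arrays, and Usp9y, Zfy1 and Zfy2 differed by -0.14, -0.29 and 0.03.

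By correlation, the arrays of a group were closer to each other than most pairs across groups, but VPA replicate 3 was an exception. Across genes, Pearson correlations between arrays of the same group lay between 0.9947 and 0.9963 and those between arrays of different groups between 0.9896 and 0.9952. VPA replicate 3 correlated with control replicate 3 at 0.9952 and with VPA replicates 1 and 2 at 0.9948 and 0.9955. Over all probe sets, the SD of its differences was 0.3, 0.294 and 0.294 to control replicates 1, 2 and 3. To VPA replicates 1 and 2 it was 0.304 and 0.311, so VPA replicate 3 lay no closer to its own group. The first principal component held 50.1% of the variance and placed control replicates 1, 2 and 3 at -21.2, -3.79 and -18.5 and VPA replicates 1, 2 and 3 at 20.2, 21.1 and 2.22. Control replicate 2 and VPA replicate 3 thus lay between the other arrays. Without both of them, a comparison of 2 against 2 arrays chosen after these scores were seen, 1349 genes changed, 416 of them among the 467, with 153 changed at least 2-fold and 13 lists past camera. Ccnd2 then differed by 1.68 (adjusted p = 0.00633). Leaving out the 2 arrays nearest the middle of the first component tends to widen the group difference, so these values add no separate evidence.

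**Figure D3:**
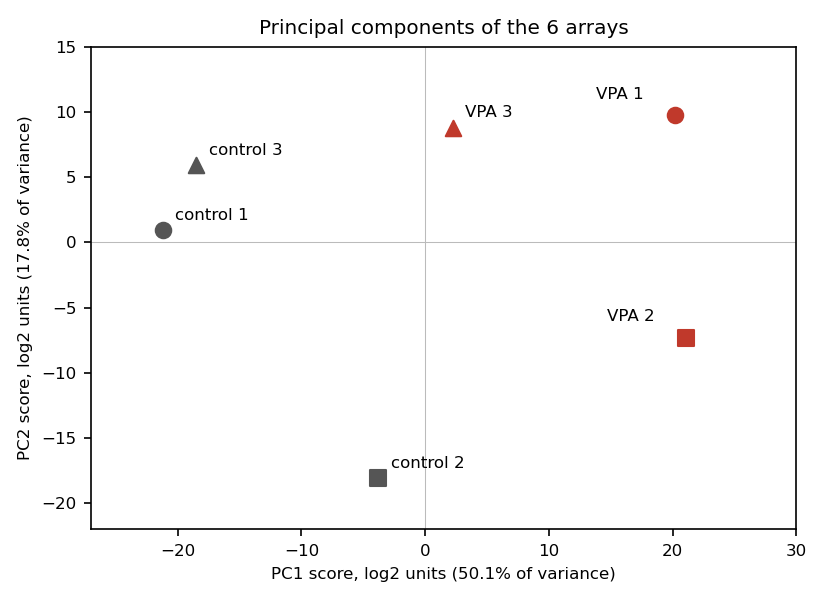
Scores of the 6 arrays on the first (horizontal axis) and second (vertical axis) principal components of the log2 values of 19938 genes, in log2 units, with 1 symbol per array. The first component, with 50.1% of the variance, places the control arrays below 0 and the VPA arrays above 0, with control replicate 2 at -3.79 and VPA replicate 3 at 2.22.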

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

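The fit without control replicate 2 and VPA replicate 3 was chosen after the data were seen, and the other settings were planned. The count of changed genes, 467 as reported, was 43 at an adjusted p under 0.01, 1199 with the replicate block, 714 with array weights, 2 with all probe sets (4372 at an unadjusted p under 0.05), 0 with the ordinary t-test (2898 at an unadjusted p under 0.05), 20 to 815 leaving out one array and 1349 without control replicate 2 and VPA replicate 3. The count of at least 2-fold changes, 52 as reported, was 2 with all probe sets, 0 with the ordinary t-test, 9 to 91 leaving out one array and 153 without control replicate 2 and VPA replicate 3. The other settings, with 471 to 683 changed genes, were within 1.5 times. With all probe sets the prior degrees of freedom went from 5.49 to 3.05, and unlisted probe sets had a median residual SD of 0.201 against 0.122. The cause was not tested for the other settings, the left-out arrays included. Same-numbered arrays had correlations of deviations of 0.0841, 0.451 and 0.284, all positive, but control replicate 1 correlated best with VPA replicate 3 (0.2). The numbers were not used as pairs in the reported fit, but pairing stays open. The glycolysis and hypoxia list followed the replicate number in both groups. With the replicate block, all 467 genes and 7 lists stayed past the threshold, and 14 named genes that had not passed gained a call. The difference of Ccnd2 was 1.13 to 1.68 over 16 settings with adjusted p from 0.00633 to 0.253, past the threshold in 10. The 1.68 and 0.00633, and 1 of the 10 passes, came from the unplanned fit without control replicate 2 and VPA replicate 3. Planned settings reached 1.54 (without control replicate 2) and 0.00841 (with the replicate block). The Ccnd2 difference was 1.34 with all probe sets (adjusted p = 0.151) and with the ordinary t-test (adjusted p = 0.253), and 1.13 to 1.54 leaving out one array. The count of lists past the threshold, 7 of 26 as reported with camera, was 0 with an estimated correlation and 0 with fry (1 and 4 at an unadjusted p under 0.05), 5 to 14 of 26 leaving out one array and 13 of 26 without control replicate 2 and VPA replicate 3. The mean of the 4 pluripotency genes stayed between -0.19 and -0.35, with no value under the low-value filter or the ordinary t-test. Other settings also gave calls to named genes that had not passed. These were 13 without control replicate 2 and VPA replicate 3, 7 without VPA replicate 3 and 5 with the trended and robust prior. Array weights and the low-value filter gave 4 each. Sign changes were limited to sex-chromosome genes that did not pass. Xist was at 0.0379 with quantile normalization and Zfy2 at -0.00374 with array weights. Leaving out arrays, the fit without control replicate 2 and VPA replicate 3 included, Xist lay between -0.112 and 0.0211, Zfy2 between -0.097 and 0.116, Kdm5d between -0.064 and 0.0125, and Eif2s3y between -0.0161 and 0.226. RMA values carry no signal over background, so low values such as those of Zfy2 cannot be told from absence.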

Other observations

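The tests of genes per chromosome, of exchanged labels, of mixing in control replicate 2 and in VPA replicate 3 by the neuronal list, of the quality of the array of control replicate 2, and of the dosage of the X chromosome were chosen after the result was seen, as were the genes named in the next paragraph.

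More genes of the fixed neuronal list rose than those named in the report. Gap43, a growth cone protein, rose by 1.25 on the log2 scale (limma adjusted p = 0.00897), and the synaptic vesicle genes Syp and Syt1 rose by 0.90 and 0.78 (adjusted p 0.0456 and 0.00973). L1cam, an adhesion molecule of axons, Map2, a microtubule protein of dendrites, the granin Scg2 and Stmn4 rose by 0.73, 0.70, 0.64 and 0.64 (adjusted p 0.0218, 0.0415, 0.0392 and 0.00973). Whether the calls of these further genes hold with an array left out was not examined. Of the 42 measured genes of the list, 32 were higher and 10 lower with VPA, and 31 did not pass. Those that did not pass included Snap25 at 0.01, Syt4 at -0.23 and Cplx2 at -0.29 (adjusted p 0.96, 0.246 and 0.152).

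The sample labels conflict. If the arrays titled VPA held undifferentiated and the others differentiated embryonic stem cells, pluripotency genes would be higher in the VPA arrays. The mean difference of Pou5f1, Nanog, Sox2 and Zfp42 was instead -0.257 (SE 0.09), which argues against that reading. Pou5f1, at 5.63 in control and 5.27 in VPA arrays, and Zfp42, at 4.36 and 4.22, lay below the lower quartile of the arrays (5.8 to 5.9). Nanog was at 6.35 and 6.14, and only Sox2 was high, at 11.6 and 11.3. A difference of strain between the groups was not tested and stays open beside the VPA treatment.

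The 467 changed genes, 52 of them at least 2-fold, came from 1 of 10 splits of the 6 arrays, and the highest count of any other split was 0 for both. For the 7 lists past camera, 4 of the 10 splits gave as many, and the highest other gave 15. With 10 splits a share under 0.05 cannot be reached. The split that puts control replicates 1 and 3 with VPA replicate 3 gave 15 lists and 3164 genes at an unadjusted p under 0.05. It differs from the real one by the exchange of control replicate 2 and VPA replicate 3.

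Control replicate 2 and VPA replicate 3 lay between the other arrays and had the 2 lowest array weights of the 6, 0.71 and 0.905. Exchanging their labels left 0 genes past limma's threshold against 467 under the titles (3164 against 3611 at an unadjusted p under 0.05), but it gave 15 lists past camera against 7. Control replicate 2 had moved 23% of the way to the VPA arrays by the genes with the largest increases and 28.1% by those with the largest decreases, which argues against an exchange for that array. VPA replicate 3 had moved 55.5% and 32.9% of the way to the controls, which by itself does not settle its label. With the first principal component removed, the weight of VPA replicate 3 was 1.69 against a median of 0.986. Control replicate 2, at 0.974, lay just below the median but above control replicate 3 (0.762) and VPA replicate 1 (0.728). Neither array thus stood out by noise outside that component. Removing the component also removes the shift that placed the arrays in between, so these weights cannot decide on quality that acts along it. Lower quality of either array stays open. VPA material at 23% or 28.1% in control replicate 2 would lift the neuronal list by 0.111 or 0.131. Its shift was -0.0117, a gap of -0.122 (SE 0.034) or -0.143 (SE 0.035). The neuronal list thus moved less than such mixing needs, but the SE is over correlated genes of a single array, not over replicates. The p53, fatty acid and mitosis lists of that array had moved toward the VPA arrays, while the DNA damage list had not. The neuronal list therefore cannot settle mixing in control replicate 2. Control material at the 55.5% or 32.9% read in VPA replicate 3 would shift the list by -0.177 or -0.0971, around the -0.142 seen. This may be a source, as may a weaker response of that culture, which was not tested. The shares from increases and decreases differed by 22.6 percentage points in VPA replicate 3 and by -5.05 in control replicate 2, where mixing needs equal shares. Control replicates 1 and 3 and VPA replicate 1, which did not lie in between, also differed (-15.5, -34.1 and -38.4). Unequal shares thus arise in such arrays as well, so this test cannot decide. Mixing in control replicate 2, in VPA replicate 3 or in both stays open.

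More X-linked genes rose than the 12.7 given by chance, at 31 of 739 (odds ratio 2.66, Fisher's exact adjusted p = 0.000268 over 40 tests of chromosomes and directions), and without control replicate 1, 2 of the 15 genes that rose were X-linked (odds ratio 3.99, Fisher's exact p = 0.11), with an odds ratio of 1.57 at an unadjusted p under 0.05 (Fisher's exact p = 0.00053). The median of X-linked genes exceeded that of autosomal genes by 0.015 (95% interval 0.00327 to 0.0316, over resampled X-linked genes, not over arrays). This argues against a shift in most of the 739 X-linked genes tested. Genes that are not expressed cannot shift, and they were not filtered out. A change of dosage seen only in expressed X-linked genes therefore stays open. The excess of X-linked genes that rose held within 10 classes of mean level (exact Mantel-Haenszel p = 7.4e-09), which argues against mean level as the whole cause. It also held without the neuronal list (Fisher's exact p = 0.00015). That list held only 4 of the 31 genes, so this cannot decide on neuronal genes outside it. Genes of the chromosome may also vary together, since 4 of 20 directions of the splits gave an X odds ratio as large at an unadjusted p under 0.05, the highest other at 4.1 against 1.42. An effect of VPA on X-linked genes stays open, as does this co-variation.

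Chromosome 9 also held more genes that rose, 36 against 20 given by chance (adjusted p = 0.00846), and chromosome 11 fewer, 9 against 26.8 (adjusted p = 0.00128). The glycolysis and hypoxia list lay at -0.36, 0.32 and 0.04 in control replicates 1, 2 and 3 and at -0.29, 0.25 and 0.04 in VPA replicates 1, 2 and 3, relative to the mean of the 6 arrays. These values followed the replicate number in both groups, so a factor shared by same-numbered arrays stays open.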
